A study of Mus musculus with 10 samples.

How the data were processed

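MC3T3 cells are a mouse calvarial pre-osteoblast line that matures in medium with ascorbic acid and beta glycerol phosphate. Per the labels and the series' design text, the cells received vehicle or 5 µM GSK126, a small-molecule inhibitor of EZH2, the catalytic subunit of Polycomb repressive complex 2 that methylates lysine 27 of histone H3. The compound was given at the start of differentiation and again 3 days later, and it was taken away on day 6. RNA was sequenced on days 3, 6 and 10, with 1 library per treatment and day (6 libraries). Chromatin immunoprecipitation of H3K27me3 was sequenced 24 hours after the first dose, together with input DNA, with 1 library of each kind per treatment (4 libraries). Each library was placed in its group by its title and treatment label.

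Per the labels' protocols, RNA came from the miRNeasy kit and the RNA libraries from the TruSeq v2 mRNA protocol, a kit that does not mark strand, while the ChIP libraries came from a NEBNext kit. The submitters' processing notes name CASAVA 1.9, BWA 0.5.9, SICER 1.1, TopHat2 2.0.6, HTSeq 0.5.3p9 and the mouse build mm10. The annotation release, the counting mode and the SICER window, gap and threshold are not given in the sources used here. The deposited gene counts are whole numbers per gene, as the authors made them, without normalization. Every deposited count was even (0 odd values in each library), so that each sequenced fragment appears to enter as 2 read ends. The deposited RPKM values equal the count divided by the coding length and by 1 total per library that is above the summed gene counts. RPKM was used here only for that check. The authors' island lists give, per island, ChIP and input read counts, a p-value, a ratio of ChIP to input scaled by 1 constant per list (fold enrichment), and an adjusted p-value, per the layout that SICER writes. Islands were called once per treatment, on 1 ChIP library against its own input.

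The table held 23358 rows and 23315 gene names. A total of 26 names occurred on 69 rows, because some names had been shortened at a full stop (Epb4 stood on 9 rows), and these rows were tested but not eligible for naming. A count of 0 in all 6 libraries was found on 4893 rows (20.9%). Total counts were 111537936 in vehicle and 107604258 in GSK126 on day 3, 104690066 and 101690602 on day 6, and 97291878 and 98285172 on day 10. Rn45s, the ribosomal RNA precursor, took 4.37% to 7.47% of the counts. No other per-sample columns were left unmapped.

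Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM normalization, filterByExpr on treatment, Benjamini-Hochberg adjusted p below 0.05), with day and treatment as additive terms. The filter left 14344 genes. With 1 library per treatment and day no single day can be tested. The treatment term averages the within-day difference over 3 days, and its 2 residual degrees of freedom measure how that difference varies between days, plus library noise. Nothing in the labels says that the libraries came from independent experiments, so p-values measure only the spread between these libraries. The biological coefficient of variation was 14.8%. A further fit added a term for treatment on day 10 against days 3 and 6, the change after removal, and had 1 residual degree of freedom. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation, camera also takes its degrees of freedom from the fit (2, or 1 for the removal term). Calls lost in that test can therefore reflect low power and not only correlation between genes. For each day, log2 ratios of TMM-normalized CPM with a prior count of 2 were taken between 1 GSK126 and 1 vehicle library, with exact binomial 95% intervals on fragments. These intervals cover counting error only. To say whether a list stood apart on a day, its median was placed among 10000 random lists of equal size matched on mean expression.

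On simulated counts for the same 14344 genes, with known genes changed in 3 simulations, the GSK126 term recovered 77.0% of 2-fold and 95.3% of 4-fold changes, and 4.08% of its calls were false. The day 10 term recovered 76.3% and 91.7%, with 6.67% false. The removal term recovered 21.0% and 76.0%, with 4.59% false. Simulated counts were drawn independently for each gene, with a spread set by expression level alone. For the GSK126 term the simulated fold was the same on every day. Differences that vary between days, and genes that move together, were not simulated, so these rates need not hold for the real libraries.

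Genes were named by a fixed rule. For GSK126 the rule took the 12 largest rises and 12 largest falls among genes with mean log2 CPM of at least 1, adjusted p below 0.05 and the same sign on all 3 days; for day 10 against day 3 it took 10 in each direction with the same sign in both treatments; for each day it took 5 in each direction among genes with CPM of 5 or more; it also took members of 25 lists (up to 4 with the smallest p, and any that passed) and 11 genes that are always given. Of 476 list entries, 455 matched a row of the table, directly or through an older symbol. The lists covered osteoblast and osteocyte genes, collagen and matrix crosslinking, Wnt ligands, feedback targets and antagonists, BMP and TGF-beta, PTH and IGF signalling, osteoclast coupling, PRC2 enzymes, Hox genes, Polycomb-silenced regulators, cell cycle inhibitors, proliferation, imprinted genes, interferon-stimulated genes, cholesterol synthesis, the stress response, and markers of adipocytes, chondrocytes, muscle, neurons, blood cells and endothelium. A list of mitochondrially encoded genes found no row and was not analysed here. The lists, naming rule, main tests and most other settings were fixed before the data were examined. Tests of gene lists on the removal term and some further tests were chosen afterwards, as stated below.

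Islands were compared by overlap of at least 1 base, with coordinates given 1-based on mm10. A gene was called marked when an island overlapped its span, because the table gives no strand; overlap code was tested on simulated intervals. The fitted difference of marked genes was compared with 10000 random lists matched on mean expression, and marked status among called genes was compared by Fisher's exact test (two-sided). Alternatives covered DESeq2 1.42.0, limma-voom, other normalizations and filters, other designs, each day left out in turn, and stricter island thresholds.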

Results

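The series measured RNA in differentiating MC3T3 pre-osteoblasts on days 3, 6 and 10, with vehicle or the EZH2 inhibitor GSK126, and H3K27me3, the repressive mark that EZH2 writes, 24 hours after the first dose. Each of the 6 RNA groups held 1 library with 97291878 to 111537936 counts, and each treatment had 1 ChIP and 1 input library. There were no replicates within a day, so errors below are standard errors (SE) of the fitted log2 difference over 3 pairs of libraries, or counting intervals of 1 pair. Each SE is the fitted difference divided by the square root of its F statistic. The spread behind that statistic is partly borrowed from other genes, so the SE is not the observed spread between the pairs.

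The first comparison asks which transcripts differ between inhibitor and vehicle in osteogenic culture. Several genes of bone matrix and mineralization were higher with GSK126 on every day. Ibsp, which encodes bone sialoprotein, was higher by 2.18 on the log2 scale (SE 0.22, 4.53-fold, n = 3 pairs), Pth1r, the parathyroid hormone receptor, by 1.33 (SE 0.17), and Smpd3, a sphingomyelinase needed for mineralization, by 2.63 (SE 0.24). Ifitm5, an osteoblast membrane protein, was higher by 3.03 (SE 0.29) and Bglap, osteocalcin, by 3.34 (SE 0.44), although reads of Bglap cannot be separated with certainty from its near-identical neighbours. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 145 genes were higher and 39 lower among 14344 tested, and all 184 had the same sign on all 3 days. Among all 14344 genes, 6429 had the same sign on all 3 days. The test itself favours genes whose difference varies little between days, so the agreement of called genes is no separate support. Adjusted p was 0.0251 for Ibsp, Smpd3 and Ifitm5, 0.0367 for Pth1r and 0.0421 for Bglap. The number of calls depended on which days were fitted: without day 3 there were 202 higher and 106 lower, without day 6 there were 18 higher and 1 lower, and without day 10 there were 4 and 0. DESeq2 called 688 and 635, and a fit with no day term called 0 in each direction (edgeR).

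Among the largest rises, Ostn, which encodes the secreted peptide osteocrin, had 0, 12 and 0 counts in vehicle and 20, 4126 and 912 with GSK126 on days 3, 6 and 10. Gpr141, an orphan receptor, had 0, 4 and 10 counts against 10, 644 and 882. With so few vehicle counts their fitted log2 differences, 8.80 and 6.81, depend on the prior count. Ostn stood at 11.88 without day 6, and neither gene was tested when counts were divided by 2. Slc36a2, a proton-coupled amino acid transporter, was higher by 4.62 (SE 0.18, edgeR adjusted p = 0.00571). The Rac exchange factor Prex1 was higher by 3.34 (SE 0.25), the sodium-calcium exchanger Slc8a3 by 3.27 (SE 0.27), and the surface glycoprotein Cd200 by 3.52 (SE 0.34). Ncf1, an NADPH oxidase subunit, rose by 3.19 (SE 0.18), heparanase, Hpse, by 3.06 (SE 0.43), the scaffold gene Iqgap2 by 4.03 (SE 0.47) and Fam167a by 3.33 (SE 0.36). Falls were smaller. Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell by 1.47 (SE 0.10, edgeR adjusted p = 0.0145). The cadherin Cdh26 fell by 1.91 (SE 0.26), Cdc42ep2 by 1.57 (SE 0.19), and Nov, a secreted CCN family protein, by 1.27 (SE 0.16). Has2, a hyaluronan synthase, fell by 1.19 (SE 0.16), the growth arrest gene Gas1 by 1.13 (SE 0.14) and the ferritin receptor Scara5 by 1.01 (SE 0.12). Fam169b, Ctxn1, Gm996 and Trim30d fell by 1.31, 1.07, 1.04 and 0.99.

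**Figure D1:**
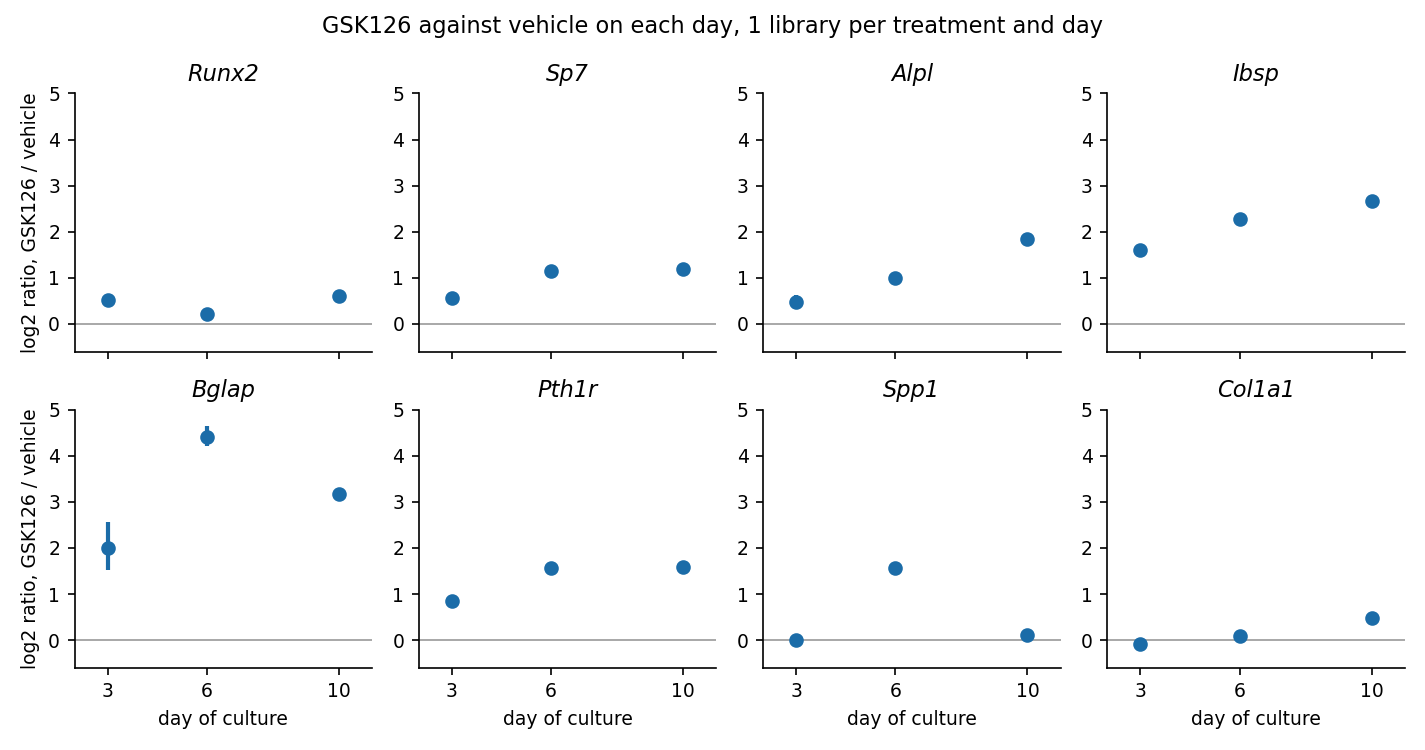
Log2 ratio of TMM-normalized CPM, GSK126 over vehicle (y axis), against day of culture (x axis) for 8 bone genes; points are 1 pair of libraries and vertical bars are 95% counting intervals, often smaller than the point. Ibsp ran from 1.60 on day 3 to 2.67 on day 10, whereas Col1a1 lay between -0.08 and 0.47.

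Other bone genes did not pass the test across all genes. Sp7, the osteoblast transcription factor osterix, had a log2 difference of 0.97 (SE 0.14, edgeR adjusted p = 0.0504), and it passed in 6 of 12 alternative fits. Runx2 stood at 0.45 (SE 0.10, edgeR adjusted p = 0.0934) and Alpl, alkaline phosphatase, at 1.11 (SE 0.26, edgeR adjusted p = 0.103). Spp1, osteopontin, stood at 0.55 (SE 0.32), with ratios of 1.57 on day 6 and 0.11 on day 10, and Col1a1 at 0.16 (SE 0.17). Leaving out 1 day put Spp1 between 0.05 and 0.85 and Col1a1 between 0.0088 and 0.29. Igf1 had -0.36 (SE 0.16), and between -0.60 and -0.18 when 1 day was left out. The transcript of the drug's target, Ezh2, stood at 0.12 (SE 0.16, edgeR adjusted p = 0.738) over all days, and at -0.09 when day 10 was left out. Cdkn2a, a common Polycomb target in fibroblasts, had 0 counts in all 6 libraries.

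Of 25 tested genes of osteoblast differentiation, 7 rose (Bglap, Ibsp, Ifitm5, Smpd3, Pth1r, Dlx3 and Enpp1), 0 fell and 18 did not pass. Adjusted over the list alone, 16 rose and 2 fell. Of all 14344 genes, 2813 had an unadjusted p below 0.05 for GSK126 by edgeR. Counts adjusted within short lists, here and below, therefore have a high background and do not show that a list stands apart. The osteoblast list was higher as a set by camera (adjusted p = 2.47e-20), and that call was lost with an estimated correlation (adjusted p = 0.466). Its median log2 ratio was 0.58, 1.01 and 1.14 on days 3, 6 and 10. The Wnt feedback list was also called higher (camera adjusted p = 0.000204, and adjusted p = 0.537 with an estimated correlation), with 2 of 11 rising: Tcf7, a transcription factor of the pathway, by 1.56 (SE 0.07), and Rnf43, a ligase that removes Wnt receptors, 2.08-fold. The median log2 ratio of the list was 0.59, -0.06 and 0.30 on days 3, 6 and 10, with 5 of 11 higher on day 6. Over the list alone, 4 rose and 0 fell. Among 7 secreted Wnt antagonists, Wif1 rose by 2.35 (SE 0.18) and Frzb from 0, 2 and 4 counts to 20, 230 and 134, while Dkk3 fell by 0.50 (SE 0.07). Over the list alone, 4 antagonists rose and 3 fell, and the camera adjusted p was 0.00749 (adjusted p = 0.627 with an estimated correlation). The BMP and TGF-beta list had 0 of 17 passing and 14 positive differences, among them Bambi, a pseudoreceptor of the pathway, at 1.15 and Bmp4 at 0.41. Adjusted over the list alone, 6 of its genes rose and 1 fell, and its camera adjusted p was 0.00834 (adjusted p = 0.603 with an estimated correlation). Without day 3, the Wnt feedback, Wnt antagonist and BMP lists no longer passed (camera adjusted p = 0.223, 0.0743 and 0.0788).

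Cartilage genes leaned the same way as the bone genes. Of 12 chondrocyte genes 0 passed across all genes and 7 rose and 1 fell when adjusted over the list alone. Col2a1, the main cartilage collagen, stood at 1.47 (SE 0.24), Matn3 at 1.40 (SE 0.23) and Hapln1 at 1.52 (SE 0.28). The list was called higher by camera (adjusted p = 2.38e-05) and by fry (adjusted p = 0.00221), and was not called with an estimated correlation (adjusted p = 0.466). All 16 genes of the integrated and endoplasmic reticulum stress list had positive differences and 0 passed, with Trib3 at 2.03 (SE 0.36) and Chac1 at 1.48 (SE 0.28). Over the list alone, 7 rose and 0 fell (camera adjusted p = 2.38e-05, and adjusted p = 0.686 with an estimated correlation). Interferon-stimulated genes were the 1 list called lower (camera adjusted p = 0.000251, and adjusted p = 0.764 with an estimated correlation). Of 21 tested, 20 had negative differences and 0 passed, and adjusted over the list alone 0 rose and 1 fell. Ddx58, a sensor of viral RNA, had -0.72 (SE 0.11), Rtp4 -1.08 (SE 0.30) and Stat2 -0.38 (SE 0.09), and Xaf1, the exception, 1.42 (SE 0.32).

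In the other 17 lists the camera adjusted p lay between 0.134 and 0.976. Among them, 2 of 40 Polycomb-silenced regulators rose (Tbx2, a T-box factor, by 1.56, SE 0.09, and Dlx3 by 1.19, SE 0.10) and 0 fell. Adjusted over the list alone, 7 rose and 9 fell. Of the 40, 14 had positive and 26 negative differences, with a median of -0.12. Among matched random lists their median lay at percentile 16.4 on day 3, 0.53 on day 6 and 1.74 on day 10, so these regulators lay low on the later days. Of 20 Hox genes, 0 passed, and adjusted over the list alone 1 rose and 0 fell. None of 13 PRC2 and H3K27 enzymes passed in either count. Osteoprotegerin, Tnfrsf11b, a decoy for the osteoclast signal RANKL, rose by 1.92 (SE 0.16) as the 1 of 7 osteoclast coupling factors to pass, and over the list alone 1 rose and 1 fell. The Wnt agonist Rspo2 fell by 0.88 (SE 0.12) among 14 Wnt ligands and agonists (over the list alone 5 rose and 1 fell). Pth1r was the 1 of 13 PTH and IGF genes to pass, with 2 over the list alone, and Gas1 was the 1 of 8 cell cycle inhibitors (over the list alone 2 rose and 3 fell). Among markers of other cell types, the smooth muscle gene Tagln fell by 0.54 (SE 0.07) as 1 of 7 muscle genes, and the neuronal tubulin Tubb3 rose by 1.76 (SE 0.21) as 1 of 7 neuronal genes. Over the list alone, 1 rose and 2 fell among muscle genes and 1 rose and 0 fell among neuronal genes. No adipocyte (4 tested), blood cell (5) or endothelial (4) gene passed across all genes, and over the list alone 1, 0 and 1 rose. The osteocyte (9), collagen (23), imprinted (11), proliferation (26) and cholesterol (19) lists had 0 genes passing across all genes. Adjusted over the list alone, 2 rose and 1 fell among osteocyte genes, 2 rose and 3 fell among collagen genes, 2 rose and 1 fell among imprinted genes, and 0 moved in the others. In 9 of the 24 lists the median, mean and test direction differed in sign, and 0 of these was a called list; the same held for the neuronal and endothelial lists between days 3 and 10.

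**Figure D2:**
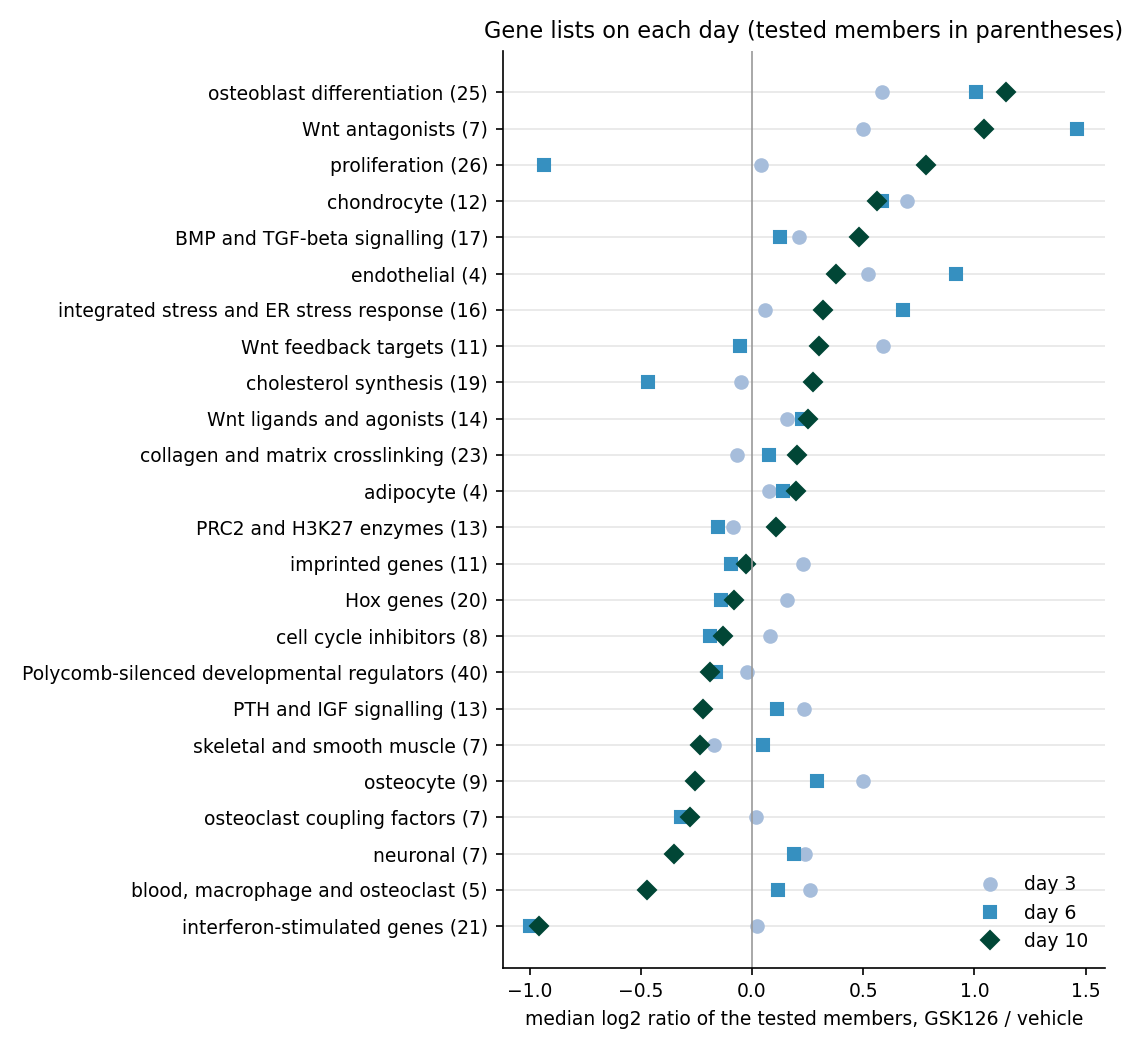
Median log2 ratio, GSK126 over vehicle (x axis), of the tested members of 24 fixed gene lists (y axis) on days 3, 6 and 10, each day 1 pair of libraries. The osteoblast list lay at 0.58, 1.01 and 1.14, interferon-stimulated genes at 0.02, -0.998 and -0.958, and proliferation genes at 0.04, -0.94 and 0.78.

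Taken day by day, the pairs of libraries give differences between libraries with no test. On day 3, 177 genes were at least 2-fold higher and 19 at least 2-fold lower with GSK126, of 11760 with CPM of 1 or more. The numbers were 490 and 244 of 11889 on day 6, and 362 and 290 of 11928 on day 10. Of the 196 genes at 2-fold or more on day 3, 93.9% had the same sign on day 6 and 86.2% on day 10, and the days have separate vehicle libraries. Across genes, which are not independent replicates, the log2 ratios of days 3 and 6 had r = 0.51, those of days 6 and 10 r = 0.53, and those of days 3 and 10 r = 0.38. On day 3 the extracellular matrix gene Abi3bp was higher by 2.81, Slc8a3 by 2.42 and Tmem56 by 2.65. Day 6 had Col9a1, a cartilage collagen chain, at 6.04 and Iqgap2 at 4.98, and among the lowest Fam131b at -2.43 and 5430419D17Rik at -2.57. On day 10 the protease gene Adamts18 stood at 5.24 and Csrnp3 at 4.83, against -3.02 for Dpt, dermatopontin, -3.33 for the interferon-inducible Ifi27l2a and -2.80 for Tulp2.

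Some named genes of single days had uneven counts across libraries. Tmem158 had 144, 184 and 2242 counts in vehicle and 58610, 148 and 44420 with GSK126. Ephx4 had 1542, 8 and 1760 in vehicle and 18, 6 and 2128 with GSK126. AB124611 had 5840 counts in GSK126 on day 10 and 114 to 260 in the others, and Inpp5e and Pcdhac2 were highest in vehicle on day 6, with 12818 and 17298 counts. The fitted GSK126 difference of these 5 genes did not pass (edgeR adjusted p = 0.287, 0.535, 0.531, 0.3 and 0.498).

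The next comparison asks whether the difference changed on day 10, after the compound was removed. No culture was kept on the compound to day 10, so removal cannot be told apart from culture time. No single gene passed: the removal term called 0 of 14344 genes by edgeR's quasi-likelihood test, with 1006 at an unadjusted p below 0.05, against 22 by DESeq2 and 0 by limma-voom. Osteoblast genes kept a median log2 ratio of 1.14 on day 10, and their removal term was not called (camera adjusted p = 0.41). Among the lists, proliferation genes moved up on day 10 relative to days 3 and 6 in 26 of 26 members, with a median of 1.24 (camera adjusted p = 3.4e-30, lost at adjusted p = 0.83 with an estimated correlation). Mcm2, a replication licensing gene, had ratios of 0.05, -0.24 and 0.77 on days 3, 6 and 10, and Pcna, the replication clamp, 0.11, -0.10 and 0.71. Cholesterol synthesis genes did the same in 19 of 19 members, with a median of 0.60 (camera adjusted p = 1.33e-15, lost at adjusted p = 0.83 with an estimated correlation), for example Lss at -0.22, -0.84 and 0.16. Interferon-stimulated genes had lower ratios on day 10 than the average of days 3 and 6 in 19 of 21, by a median of -0.59, although the day 6 and day 10 medians were close (-0.998 and -0.958) (camera adjusted p = 0.000581, lost at adjusted p = 0.83 with an estimated correlation), and PTH and IGF genes in 9 of 13, by -0.50 (camera adjusted p = 0.0248, lost at adjusted p = 0.83 with an estimated correlation). In these 4 lists 0 members passed across all genes. The other 20 lists had camera adjusted p between 0.0757 and 0.805. Over the list alone, 0 of the proliferation and interferon genes passed, 4 cholesterol genes rose and 1 PTH and IGF gene fell.

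The culture time course, averaged over both treatments, gave larger numbers. Library composition moved with it, since Rn45s took 4.37% and 4.44% of the counts on day 3 and 7.24% and 7.47% on day 10 in vehicle and GSK126. The largest falls between days 3 and 10 included several genes of the immediate early type, which were not tested as a group: Fos fell by 5.87 (SE 0.28), Egr2 by 4.65, Egr1 by 4.38, Ier2 by 3.82, Arc by 3.30, Zfp36 by 3.11 and Egr3 by 2.81. Chodl, Suv420h2 and Sox11 fell by 3.36, 2.68 and 2.64. The largest rises included the bone genes Bglap, higher by 5.66, Bglap2, by 5.52, and Mmp13, a collagenase, by 4.99, next to Slc36a2 at 7.43, Rab11fip4 at 5.40, Itgbl1 at 4.94 and Prex1 at 4.89. Gpr141, Fgf14 and Aqp2 also rose, from 0, 2 and 10 counts in vehicle and 10 each with GSK126 on day 3 to 10, 444 and 1116 in vehicle and 882, 402 and 384 with GSK126 on day 10, too few at the start for an exact fold. In all, 2026 genes were higher and 1793 lower on day 10 than on day 3, and 74 were higher and 34 lower on day 6 than on day 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). With library size in place of TMM the median of all genes moved to -0.107 for day 10, and the share of calls that were higher was 35.9% in place of 53.1%. Without day 10, 19 genes were lower on day 6.

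As groups, 15 of 25 osteoblast genes rose and 2 fell between days 3 and 10 (the same adjusted over the list alone), with Dlx3 at 2.28 and Omd, osteoadherin, at 2.42 (camera adjusted p = 6.69e-13, lost at adjusted p = 0.47 with an estimated correlation). All 19 cholesterol synthesis genes fell, by a median of 1.67, among them Insig1, which holds back sterol synthesis, by 1.72 (camera adjusted p = 3.99e-25, lost at adjusted p = 0.47 with an estimated correlation; adjusted over the list alone also 19). Of 7 muscle genes 5 fell, including Acta2 by 1.37 (camera adjusted p = 0.00485, lost at adjusted p = 0.47 with an estimated correlation), and of 7 Wnt antagonists 3 rose, including Wif1 by 2.52 (camera adjusted p = 0.00801, lost at adjusted p = 0.47 with an estimated correlation). Those counts were the same adjusted over the list alone. Interferon-stimulated genes fell in 3 of 21, including Isg15 by 1.02 (camera adjusted p = 0.0273, lost at adjusted p = 0.697 with an estimated correlation), and in 0 when adjusted over the list alone. Of all 14344 tested genes 1793 fell, so 3 of 21 is close to the share over all genes. Imprinted growth genes Igf2 and H19 rose by 4.02 and 4.22, in a list that was not called (camera adjusted p = 0.0993). The 19 lists without a call had camera adjusted p between 0.0574 and 0.91.

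The ChIP data address where H3K27me3 lay after 24 hours. The authors' lists held 34498 islands over 147.9 Mb in vehicle and 24947 islands over 166.7 Mb with GSK126. Of the vehicle islands 60.4% overlapped a GSK126 island, and 82.28 Mb was shared. The median island was 3400 bases long in vehicle and 5600 with GSK126. Fold enrichment, the authors' own value for each island against its own input, had a median of 2.48 (quartiles 2.05 and 3.06) in the vehicle list, where 9324 islands reached 3, and of 2.04 (quartiles 1.76 and 2.38) in the GSK126 list, where 1453 did. At a fold of 2 or more the lists held 26955 and 13398 islands, over 116.8 and 86.64 Mb, which turns the order of covered length. With 1 ChIP library each there is no test between treatments, and the islands with most ChIP reads lay in regions where input was also high, such as chromosome 9 from 2999801 to 3038400 (24290 ChIP and 29263 input reads in vehicle, fold 1.39) and chromosome 11 from 3126801 to 3200000, over Pisd-ps1 and Sfi1 (fold 0.821). Coverage was uneven between autosomes, from 0.975% of chromosome 14 to 16.3% of chromosome 19 in vehicle.

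**Figure D3:**
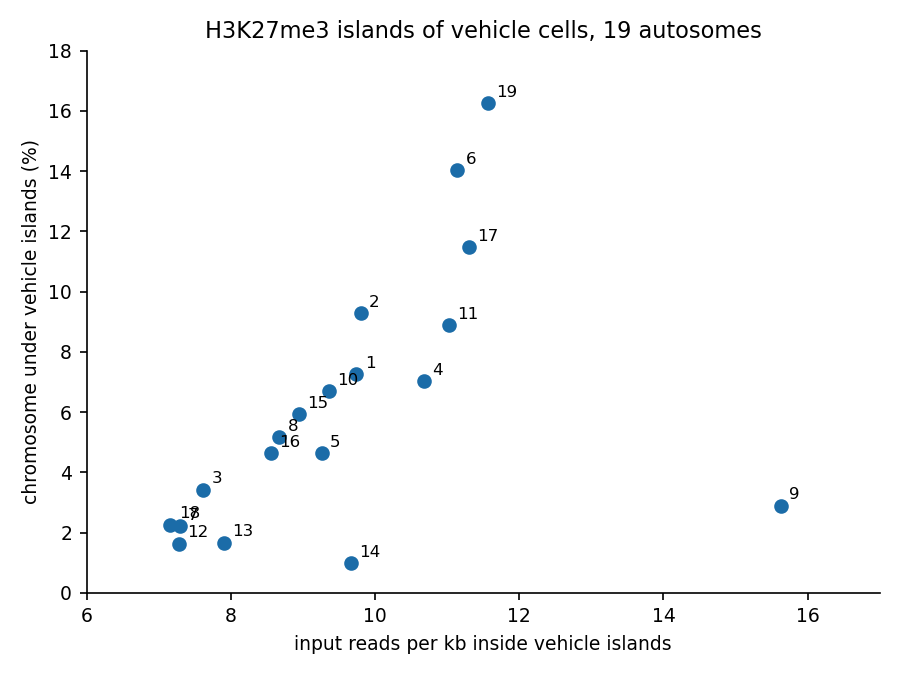
Percent of each autosome under vehicle H3K27me3 islands (y axis) against input reads per kb inside those islands (x axis), 1 point per autosome. Spearman's rho was 0.698 over 19 autosomes.

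Genes under vehicle islands were more often silent: of 3991 such genes, 45.6% had 0 counts in vehicle on day 3, against 25.9% of 19367 others. Several of the genes with the largest rises were marked. In vehicle, islands lay within Ostn (chromosome 16, 27347601 to 27350200, fold 2.87) and Gpr141 (chromosome 13, 19803601 to 19806400, fold 3.01), where the GSK126 list had no island. These islands were small, with 29 and 34 ChIP reads against 17 and 19 input reads. Islands differed in both directions: 404 tested genes had one in vehicle alone and 199 with GSK126 alone. Slc36a2 (chromosome 11, 55158468 to 55185077) held islands in both lists, with folds of 2.14 and 2.24 in vehicle and 2.61 at both islands with GSK126, and Prex1 and Col9a1 also held islands in both. Among the fixed lists, 8 of 11 Wnt antagonist genes carried a vehicle island and 4 a GSK126 island, whereas 1 of 25 osteoblast genes did in each list. Of all genes in the table, 17.1% carried a vehicle island. Wnt ligands and agonists (8 of 21 in vehicle and 10 with GSK126) and PRC2 and H3K27 enzymes (0 of 13 and 1) went the other way.

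The last comparison joins both assays and asks whether marked genes differed in expression. Of 145 genes higher with GSK126, 58 overlapped a vehicle island, against 9.17% of all tested genes (Fisher's exact test, odds ratio 6.86), and 0 of the 39 lower genes did (Fisher's exact p = 0.0465, but p = 0.412, 0.11 and 0.629 with 3 other definitions of marked genes). Marked genes were longer, with a median span of 42.6 kb against 18.8 kb. Random genes matched on expression and span held 26 marked of 145 (18 to 33 in the middle 95%, and 39 at most), and 1 of 39 (0 to 3), a range that holds the 0 of the lower genes. Over all 1316 marked genes the median log2 difference was 0.18, against 0.03 for lists matched on expression, above all 10000 random lists. It was 0.37 on day 3, 0.25 on day 6 and 0.03 on day 10, against 0.09, 0.05 and -0.06 for matched lists. Genes without an island in the GSK126 list did not stand out among them. Of 404 tested genes with an island in vehicle and none with GSK126, 15 were called higher (Fisher's exact test, odds ratio 4.1). Their median log2 difference was 0.15, against 0.03 for matched lists.

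**Figure D4:**
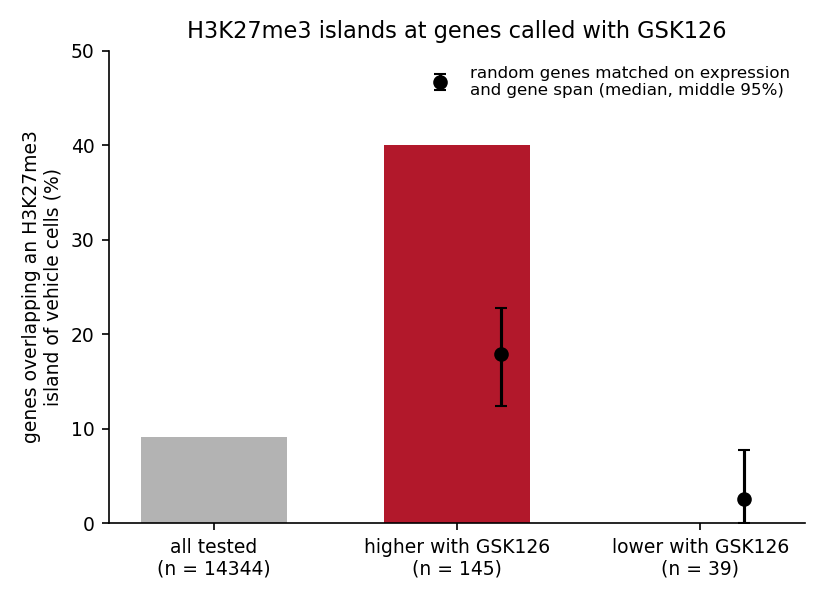
Percent of genes whose span overlaps an H3K27me3 island of vehicle cells (y axis) for all 14344 tested genes, the 145 higher and the 39 lower with GSK126 (bars); black points and whiskers give the median and middle 95% of 10000 random gene sets matched on expression and gene span. Of the higher genes 58 overlap an island and of the lower genes 0.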

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

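The tests of gene lists across the removal of the compound were chosen only after the day values were seen. Proliferation genes differed between day 10 and days 3 and 6 by a median log2 of 1.24 in the GSK126 against vehicle ratio, by the interaction term, with the sign turning from -0.94 on day 6 to 0.78 on day 10. Over the 3 days together the list showed no difference (camera adjusted p = 0.976), but without day 6 it was called higher (camera adjusted p = 1.91e-08) and without day 10 lower (camera adjusted p = 5.12e-05). Cholesterol synthesis genes differed by 0.60 in the same term, with medians of -0.47 on day 6 and 0.28 on day 10, and without day 10 that list was called lower (camera adjusted p = 0.000732). PTH and IGF signalling genes differed by -0.50, with medians of 0.23, 0.11 and -0.22 on days 3, 6 and 10, including Igf2 at 1.21, 1.62 and 0.12 and the binding protein Igfbp5 at 0.23, -1.24 and -1.45. These 3 calls were lost with an estimated correlation (adjusted p = 0.83 for each), and each day is 1 pair of libraries.

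Among single genes named for a day, Sap30l and Gm15706 turned by 2-fold or more in opposite directions on different days, differences that were not tested. Sap30l, a subunit of a histone deacetylase complex, had a log2 ratio of -4.50 on day 6 and 3.28 on day 10, a gap of 7.78, and its counts were 61378 in vehicle on day 6 and 26558 in GSK126 on day 10, against 2468 to 3052 in the other libraries. Gm15706 had 2.75 on day 3 and -2.82 on day 10, a gap of 5.57.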

How the results depend on the processing

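Counts divided by 2, fits without Rn45s, islands with adjusted p of 0.01 or less, gene ends in place of spans, islands in vehicle alone and span-matched random lists were chosen after seeing the data. The planned windows around transcription start sites were not run, because no strand was used, and overlap with the gene span became the main definition. Treatments were paired by day through the day term, and no pairing by replicate number was possible because each group has 1 library. Over all results, 608 of 751 alternative values kept their side of the threshold or stayed within 1.5-fold, and 1 reversed: Ezh2 ranged from -0.093 without day 10 to 0.308 without day 6. Of 393 values for single GSK126 genes, 79 lost and 8 gained the call. DESeq2 called 688 higher and 635 lower genes with GSK126, 998 and 744 for day 6 against day 3, and 22 for removal. Limma-voom called 59 lower, no filter 63 lower (52 lower on day 6), and library size alone 74 lower on day 6. The main tests ran on the deposited counts. With counts divided by 2, 135 genes were higher and 30 lower with GSK126. On that scale 50 were higher and 23 lower on day 6, and 2008 higher and 1869 lower on day 10. Without a day term 0 were higher and 0 lower with GSK126; without a treatment term 837 were higher and 649 lower on day 10, and 0 and 1 on day 6. Leaving out 1 day gave 4 to 202 higher and 0 to 106 lower genes with GSK126, 19 lower genes on day 6 without day 10, 5 to 11 called lists for GSK126 and 10 for day 10, where fewer libraries were fitted. Without day 3, 103 of the 145 higher and 13 of the 39 lower calls remained. An estimated correlation left 0 called lists for GSK126 and 0 for day 10, and fry 1 and 1. The test with an estimated correlation also ran on the few residual degrees of freedom of the fit. Its lost calls therefore do not separate correlation between genes from low power. With CPM of 5 or more, where fewer genes are compared, 74 genes were 2-fold higher and 9 lower on day 3, 269 higher on day 6, and 232 higher and 163 lower on day 10. At a fold of 2 or more the GSK126 list kept 13398 islands over 86.64 Mb and 37.9% of vehicle islands overlapped it. At 3 or more the lists held 9324 and 1453 islands over 33.43 and 6.379 Mb, overlap was 4.64% and the GSK126 median fold 3.29. At adjusted p of 1e-10 or less they held 11361 and 9520 islands over 71.79 and 84.02 Mb, and at 5 kb or longer 8743 and 15524, with 71.5 Mb in vehicle. These stricter lists hold fewer islands by construction; the cause of the other changes was not tested. The difference of marked genes stayed above matched lists in all 11 alternatives (0.03 to 0.37). With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. Only 1 split, the real one, gave as many as its 184 called genes, and the highest other gave 0. Some splits put both libraries of a day in the same group, which a comparison paired by day cannot exchange. All splits but the real one also leave the treatment difference within groups, so their 0 calls are no separate support. Depth limits genes with few counts, such as Ostn, Gpr141 and Frzb, whose vehicle counts were 0 on day 3.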

Other observations

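The tests on day 6 against the vehicle time course, and of the vehicle against the GSK126 share of each chromosome, were chosen only after related values were seen. Islands were found at some marker genes of other lineages, which was not tested and not matched on gene span. In vehicle, 7 of 13 neuronal genes, 6 of 12 adipocyte genes, 6 of 13 blood cell genes and 24 of 71 Polycomb-silenced developmental regulators overlapped an island, against 17.1% of all genes in the table. Shares nearer to that value were found for Hox genes (8 of 39), chondrocyte genes (3 of 14) and interferon-stimulated genes (3 of 23). None of the 23 collagen, 26 proliferation or 10 cell cycle inhibitor genes did. A few loci had counts present in a single library: Mir2137 had 45208 counts in vehicle on day 10 and at most 4 in the others, and Accn1 had 13154 counts in GSK126 on day 10 and 0 in the others.

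In the fitted terms, the GSK126 differences ran with the differences between days. Of the genes called higher with GSK126, 99 were also higher on day 10 than on day 3 (20.5 for independent lists) and 12 lower (18.1), and of those called lower 19 were also lower (4.88) and 1 higher (5.51). Both terms come from the same libraries, and the fitted differences had r = 0.32 and covariance 0.134 across genes. In 20 simulations without a treatment effect, r lay between -0.029 and 0.028 and covariance between -0.0063 and 0.0062. With 1 library per treatment and day, both terms are balanced against each other, so a small simulated r was fixed in advance. The simulations therefore test neither shared libraries nor noise common to many genes. Between comparisons that share no library, the day 6 GSK126 difference against vehicle day 10 minus day 3 had r = 0.294, which argues against shared libraries as the whole cause, and 0.285 after trends with coding length and expression were removed, which argues against those trends. Without the osteoblast, osteocyte, collagen and Wnt genes r was 0.288 on day 6. The largest of these lists hold 25 and 23 of 14340 genes, so leaving them out could hardly move r on any day. That step cannot separate a general advance along the culture time course from an effect on those genes. For day 6 a general advance stays open as a hypothesis, as do effects of the inhibitor unrelated to timing. On day 3, against vehicle day 10 minus day 6, r was 0.0448 (0.0351 after removing trends, too small to decide on them) and 0.0394 without those lists, which is below the bound set for a general advance and within that set for shared libraries, and on day 10, against vehicle day 6 minus day 3, r was -0.0247 (Spearman's rho = -0.145).

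The GSK126 islands covered more bases than the vehicle islands while their median fold was lower. They were also fewer (24947 against 34498) and longer (median 5600 against 3400 bases). From 49 islands with identical bounds, the GSK126 ChIP library was estimated to be 1.256 times as large as the vehicle one, above the bound set for a deeper library. Greater depth may therefore account for the wider coverage, but whether it can go with fewer islands was not tested. In the 49 islands with identical bounds the median log2 ratio of fold enrichment, GSK126 over vehicle, was -0.0906 (quartiles -0.587 and 0.178), which does not decide whether enrichment differed. Islands present in both lists also cannot show islands that were lost. A change in the mark itself cannot be told apart from library quality with 1 ChIP library per treatment.

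Islands were spread unevenly over chromosomes: they covered 16.3% of chromosome 19 and 14.0% of chromosome 6 in vehicle, against 2.22% of chromosome 7 and 0.975% of chromosome 14. The GSK126 list gave nearly the same order (rho = 0.9895 over 19 autosomes, permutation p = 1e-05, the smallest the permutations can give), which argues against chance in 1 ChIP library. Input reads per kb inside vehicle islands went with the share covered (Spearman's rho = 0.698, permutation p = 0.0012, adjusted 0.0016 over 4 relations; Pearson's r = 0.454, permutation p = 0.052, adjusted 0.069, and r = 0.83 without the 2 chromosomes of most extreme input), and the relation was weaker in the GSK126 list (rho = 0.57, permutation p = 0.013; r = 0.246, permutation p = 0.3). Input was counted only inside islands, where a lower fold goes with more input per ChIP read, so this relation cannot by itself show chromosome copies. Whether extra copies of chromosomes such as 6 and 19 in this cell line raise the number of weak islands stays open. Chromosome 6 held 12.1% of autosomal vehicle islands but 5.21% of those with a fold of 4 or more. Gene density and the mark's own distribution were not tested.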
